A study of Mus musculus with 10 samples.

How the data were processed

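H2A.Z, a variant of the core histone H2A that sits in nucleosomes around many promoters and enhancers, was profiled by CUT&RUN in primary mouse brown adipocytes. In CUT&RUN an antibody bound to chromatin recruits a nuclease, and the DNA that the nuclease releases is sequenced. Per the labels, the cells were isolated from brown adipose tissue of wild-type mice kept for 4 h at thermoneutrality or at 5 °C and were fixed with formaldehyde. The labels call the cells unstimulated or stimulated through the β3-adrenergic receptor, the receptor through which cold-evoked noradrenaline acts on brown fat. Read literally, the sentence in the labels that pairs housing with stimulation puts thermoneutrality with the stimulated cells. Against that order, the 5 °C animals were taken here as the stimulated ones, from general knowledge of cold exposure. The 10 libraries comprised 3 unstimulated and 3 stimulated H2A.Z libraries and 2 unstimulated and 2 stimulated IgG controls. The grouping came from the labels.

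The deposited data used here were 2 peak lists, 1 per condition, with no value per library. Whether the libraries of a condition were pooled before peaks were called, and whether the IgG libraries entered the calling, is not stated in the labels. The IgG libraries were therefore not analysed here, and no background measured in the same way stands beside the H2A.Z values. The submitters' processing notes name the genome build mm10 and deepTools 3.3.1, with no role given for that tool. The aligner and the peak caller are not given in the sources used here. Per the file headers, the deposited columns give each peak's position, a summed signal, a height, which is the highest signal within the peak, and a logP of that height. The logP column was checked against the values and is the −log10 of an upper-tail Poisson p-value of the whole-number part of the deposited height. A single Poisson mean of 1.84 reproduced it in each list, so the signal of both lists appears to have been scaled to one total. The deposited signal is otherwise in arbitrary units, and the sequencing depth is unknown. The heights and −log10 p-values are the authors' own and were used to rank and filter peaks within a list.

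The labels give 3 H2A.Z replicates per condition, but the lists carry no spread between them. No comparison in the report has a replicate check, and no p-value between conditions was computed. Differences between the lists describe these lists, in which the condition, the quality of the libraries and their depth are not separated. Intervals on shares are 95% Wilson binomial intervals over peaks and cover counting error only.

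A peak was called overlapping when at least 1 bp of it lay in a peak of the other list, and otherwise was assigned to one list only. The overlap was set beside that after 100 circular shifts of the unstimulated list within each chromosome. The longer list was also shortened to the length of the other by −log10 p. Overlapping peaks of both lists were merged into shared regions, and the log2 ratio of the tallest stimulated to the tallest unstimulated height was taken per region. This ratio was not among the analyses fixed before the data were examined. It was added once the common Poisson mean was seen. The plan had ruled out setting fold or q values of the lists against each other, so setting heights side by side departs from its intent and rests on that scaling.

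Gene positions came from a table of mouse RefSeq genes on GRCm38.p6, the same build as mm10, which gives gene start and end but no strand, exons or transcription start sites. The planned windows around transcription start sites were therefore replaced by 1 kb on each side of both annotated gene boundaries, so a boundary peak can lie at either end of a gene, and promoters inside a gene are missed. Peaks whose midpoint lay in such a window were classed as boundary peaks and the others as inside or outside genes, with 200000 random positions for comparison. A gene was given the tallest peak that overlapped either of its windows by at least 1 bp. Exons and introns were not separated. For the same reason the matching of random gene lists on promoter GC was replaced by quartiles of transcript number and gene length, and the motif analysis was not run. Coordinates are those of the deposited lists, which lie on a grid of 10 bp.

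Of 533 names in the 22 gene lists fixed before the data were examined, 529 matched the table, 522 by symbol and 7 by a synonym, giving 514 different genes. The lists covered the thermogenic program, β-adrenergic and cAMP signalling, immediate early genes, lipolysis and lipid droplets, adipocyte transcription factors, fatty acid oxidation, the respiratory chain, de novo lipogenesis, glucose use, creatine and calcium cycling, H2A.Z deposition and removal, chromatin loop architecture, heat shock and isolation stress, housekeeping genes, developmental polycomb targets and markers of 7 other cell types. Each list's number of genes with a boundary peak in one list only, and its median log2 height ratio, were placed as a percentile among 10000 random lists of the same size. Random lists for the ratio were drawn from genes with peaks in both lists, matched on deciles of mean height. A percentile under 2.5 or above 97.5 was taken as standing apart.

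The genes and regions to be named were also fixed by rule. These were 10 genes chosen by name, up to 6 genes per list and direction with a boundary peak in one list only, the 10 genes per direction with the highest −log10 p of a one-list boundary peak and no peak of the other list within 5 kb, the 5 highest one-list peaks per direction more than 10 kb from a gene boundary, and the 5 tallest peaks per list. Genes named outside this rule are marked where they appear.

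The overlap code was tested on simulated lists with 6063 added and 17914 removed peaks and recovered all of them. The list percentile was tested on 30 simulated lists of 20 genes. With no shift 3.33% of the lists lay above percentile 97.5, and with shifts of 0.1, 0.2 and 0.3 on the log2 scale 13.3%, 60.0% and 100.0% did. Without a shift 10.0% lay outside the range from 2.5 to 97.5. Alternatives were other overlap definitions, list lengths, gene windows and random lists, and, chosen after the data were seen, a −log10 p of at least 20, a height of at least 30, whole gene spans and rescaled stimulated heights. The planned limits of −log10 q 5 and fold 4 could not be applied as such, and their nearest equivalents removed no peak, the lowest −log10 p being 10.8 in both lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.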

Results

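The data comprised 2 lists of H2A.Z peaks from primary mouse brown adipocytes, 1 from unstimulated cells and 1 from cells stimulated through the β3-adrenergic receptor, for each of which the labels give 3 H2A.Z libraries. The comparison between the lists addresses where H2A.Z is incorporated in the genome in each state. All values below come from single lists without replicates, and heights are the authors' normalised signal in arbitrary units.

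More and longer H2A.Z peaks were listed in stimulated than in unstimulated brown adipocytes. The stimulated list held 69809 peaks over 40.7 Mb and the unstimulated list 59169 peaks over 29.4 Mb, a ratio of 1.18 in number and 1.38 in covered length. Peaks longer than 1 kb numbered 13325 and 8482. Peaks taller than 100 numbered 3184 in the stimulated and 999 in the unstimulated list. The median peak length was 320 bp in stimulated and 280 bp in unstimulated cells, and the median height was 24.0 and 23.3. The mean signal per covered bp was 35.5 in the stimulated and 31.0 in the unstimulated list, and the summed signal stood in a ratio of 1.59.

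Most tall H2A.Z peaks occupied the same places in both states, and the peaks found in one state only were low and short. Of the stimulated peaks 36036 (51.6%, 95% Wilson interval 51.3 to 52.0) overlapped an unstimulated peak and 33773 did not. Of the unstimulated peaks 43183 (73.0%, interval 72.6 to 73.3) overlapped a stimulated peak and 15986 did not. After circular shifts of one list a mean of 2.15% of stimulated peaks overlapped, with a range from 1.98% to 2.37% over 100 shifts. Of the highest-ranked 10% of peaks 99.9% were shared in either list. Stimulated-only peaks had a median height of 19.7 and a median length of 150 bp, against 37.5 and 730 bp for the shared stimulated peaks. Unstimulated-only peaks had medians of 18.98 and 110 bp, against 27.3 and 410 bp. A peak of the other list lay within 1 kb of 41.6% of stimulated-only and 50.5% of unstimulated-only peaks. When the stimulated heights were divided by their median ratio to the unstimulated heights of 1.28 and peaks under the lowest unstimulated height were left out, 45413 stimulated peaks stood against all 59169 unstimulated ones. With the stimulated list so shortened, 13855 peaks were stimulated-only and 19008 unstimulated-only.

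**Figure D1:**
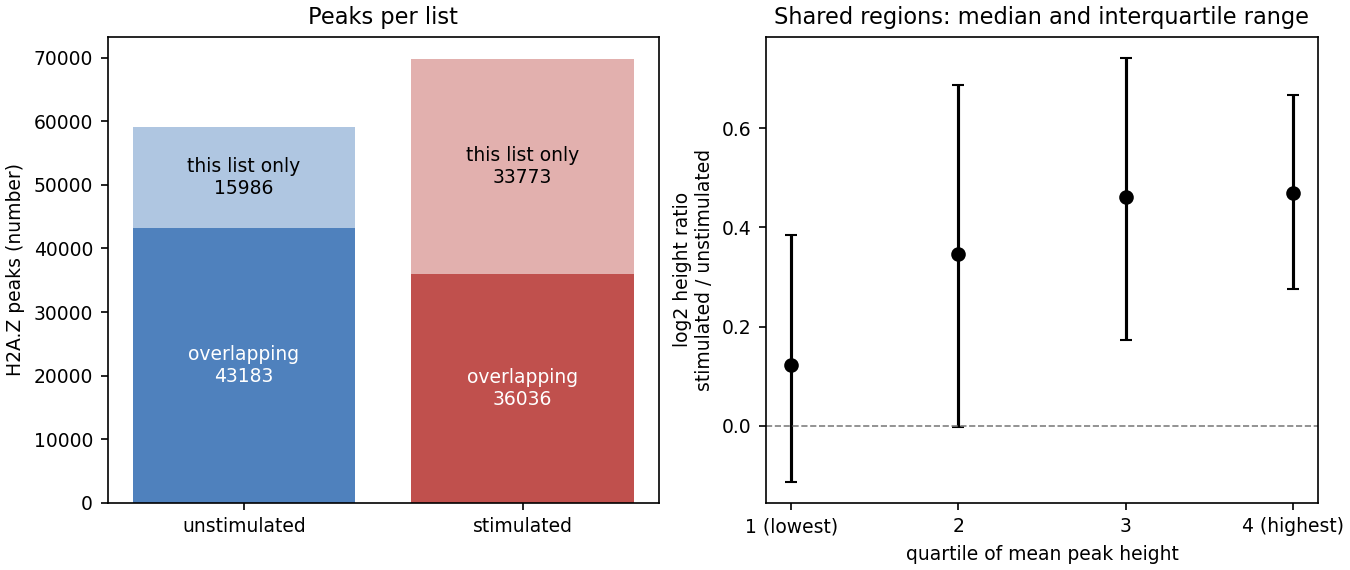
Left, number of H2A.Z peaks (y axis) in each list, split into peaks overlapping the other list by at least 1 bp and peaks of that list only, with 33773 stimulated-only and 15986 unstimulated-only peaks. Right, log2 ratio of stimulated to unstimulated peak height (y axis) in shared regions by quartile of mean height (x axis), where points are medians and bars interquartile ranges, from a median of 0.12 in the lowest to 0.47 in the highest quartile.

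With both lists held at 59169 peaks, 24738 peaks (41.8%) were stimulated-only and 16883 (28.5%) unstimulated-only. At equal length this difference is the same as that between the overlapping peaks, 34431 in the stimulated and 42286 in the unstimulated list, and so is not a separate measure of a gain. In the whole lists 1 stimulated peak covered 2 or more unstimulated peaks in 6986 shared regions, and 1 unstimulated peak covered 2 or more stimulated peaks in 1762. Among the 10000 highest-ranked peaks of each list, 18 stimulated and 23 unstimulated peaks lacked an overlap with the whole other list.

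At regions occupied in both states, H2A.Z peaks were mostly taller and longer in the stimulated list. Over 33178 shared regions the median log2 height ratio was 0.36, or 1.28-fold, with an interquartile range from 0.07 to 0.63. The stimulated peak was the taller one in 79.5% of regions. A height at least 2-fold greater was found in 1945 regions in the stimulated list and in 93 in the unstimulated list. Where exactly 1 peak of each list overlapped, in 23682 pairs, the median length was 660 bp in the stimulated and 450 bp in the unstimulated list. The ratio differed with height, from 0.12 in the lowest to 0.47 in the highest quartile of mean height. These are heights of separately called peaks without replicates, so it is not known how far libraries of one condition would differ.

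H2A.Z peaks clustered at the ends of genes, and the peaks of one state only lay there less often than the shared ones. Within 1 kb of a gene boundary lay 34.0% of shared and 13.6% of stimulated-only peaks of the stimulated list (intervals 33.5 to 34.4 and 13.3 to 14.0). In the unstimulated list the shares were 35.2% and 8.46% (intervals 34.8 to 35.7 and 8.04 to 8.91). Random positions fell there in 3.05% of cases. Stimulated-only peaks lay inside genes in 30.1% and outside genes in 56.3% of cases, unstimulated-only peaks in 36.3% and 55.3%, and random positions in 38.4% and 58.6%.

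The tallest peaks were common to both lists. On mm10 these included chromosome 19, 61266340 to 61267650, outside genes and 38.5 kb from Csf2ra, with heights of 933.7 in the stimulated and 702.7 in the unstimulated list, and chromosome 1, 195241560 to 195242710, 65.3 kb from the complement receptor gene Cr2, with 884.1 and 680.7. A peak at chromosome 1, 88276020 to 88281810, covered a boundary of Hjurp, which encodes the chaperone of the centromeric histone. Its centre lay 1.27 kb from that boundary, and its heights were 604.3 and 409.2. Distances to genes are measured from the peak centre. The other 2 of the 5 tallest peaks in each list lay on the mitochondrial sequence. Among stimulated-only peaks more than 10 kb from a gene boundary, the highest lay at chromosome 15, 75086470 to 75086580, 21.6 kb from Ly6c2, with a height of 95.5. Further ones lay 171 kb from Samd9l (height 87.4), 15.8 kb from Gtpbp4 (82.9), 36.7 kb from the kinase gene Cdk17 (68.3) and inside Hip1r (63.6). The highest unstimulated-only distal peak lay inside the ion channel gene Trpm3 at chromosome 19, 22281430 to 22281640, with a height of 80.1. The others were 2 peaks inside Sfi1 (64.9 and 55.3), 1 inside Plekha7 (59.3) and 1 at 67.0 kb from Bod1 (58.4). A peak of the other list lay 0.28 kb from the Ly6c2 peak, 0.29 kb from the Gtpbp4 peak and 0.35 kb from the Plekha7 peak. None of the peaks named here was filtered in the re-analysis for artefact-prone regions or against IgG.

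Most genes with H2A.Z at their ends had it in both states, and among the rest stimulated-only genes outnumbered unstimulated-only genes by 5.54 to 1. Of 21887 protein-coding genes, 11942 had a boundary peak in both lists, 1251 in the stimulated list only, 226 in the unstimulated list only and 8468 in neither. The boundary peaks of stimulated-only genes were lower, with a median height of 24.0, than those of genes with peaks in both lists, at 69.1. The lowest height was 16.0 in either list. For a low one-list peak, absence from the other list therefore cannot be told from a signal just under the cutoff. In genes with peaks in both lists the median log2 ratio was 0.48 (1.39-fold). The stimulated peak was taller in 91.7% of them, by at least 2-fold in 893, while the unstimulated peak was at least 2-fold taller in 14. The counts were 1653 stimulated-only and 141 unstimulated-only genes at a −log10 p of at least 20, and 887 and 376 with rescaled heights.

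The most prominent stimulated-only boundary peaks included one at chromosome 18, 38600320 to 38601760 (height 63.2). It spanned the neighbouring ends of Arhgap26 and Spry4, an inhibitor of receptor tyrosine kinase signalling. Another lay at Atp2a2, the calcium pump of the endoplasmic reticulum, at chromosome 5, 122502470 to 122503800 (57.5). One peak served Fes and the protease gene Furin (56.1). Peaks at Kifbp (57.0), Irf9, a transcription factor of the interferon response (54.4), the proton pump subunit gene Atp6v1e1 (52.5), Fxyd7 (51.8) and Gmip (49.6) completed this group, taken from 865 genes with no unstimulated peak within 5 kb. The unstimulated-only group was taken from 128 such genes and led by Trarg1, a regulator of the glucose transporter GLUT4 in fat cells, at chromosome 11, 76678800 to 76679540 (height 43.6). The translation factor gene Eif4a1 (29.0), 4933417A18Rik (34.0), Nipal4 (28.8), Rnase13 (28.9), Lamb3 (27.9), Acot5 (26.4), Atp2c2 (26.9), Iho1 (26.1) and Il1rapl1 (26.1) followed.

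At the genes best known in brown fat, H2A.Z peaks were listed at Dio2 in stimulated cells only, were taller in stimulated cells at Ppargc1a, Pparg, Prdm16 and Elovl3, and were not listed at Ucp1. The log2 ratios of the tallest peaks over the gene span of Ppargc1a (0.66), Prdm16 (0.69) and Elovl3 (0.62) lay within the interquartile range of the same ratio over all genes, 0.24 to 0.69, and that of Pparg (1.81) lay above it. At its boundaries Ppargc1a had 46.3 and 28.3, a log2 ratio of 0.71 against an interquartile range from 0.25 to 0.70, and Prdm16 had a boundary peak in the stimulated list only. Dio2, the deiodinase that activates thyroid hormone, had 7 peaks over its span with 1 kb on each side, the window used for all peak counts given here, in the stimulated list, the tallest 35.4, and none within 10 kb in the unstimulated list (chromosome 12, 90724552 to 90739038). Apart from the tallest, these Dio2 peaks reached at most 20.3 and went down to 16.4, near the lowest stimulated height of 16.0. Ppargc1a, the coactivator of mitochondrial biogenesis, had 28 stimulated peaks over 13870 bp and 21 unstimulated peaks over 8060 bp, with tallest heights of 230.6 and 146.2. The boundary peak of Pparg, the master regulator of fat cells, was 70.5 tall in the stimulated and 20.2 in the unstimulated list, a ratio of 3.50. Prdm16, a determinant of brown fat identity, had 7 stimulated and 3 unstimulated peaks, the tallest 39.4 and 24.4. Elovl3, a fatty acid elongase induced by cold, had 76.5 and 49.6, and Pdk4, an inhibitor of pyruvate oxidation, 108.1 and 75.8, the latter ratio of 1.43 being close to the median of all genes. Neither Ucp1, the uncoupling protein of brown fat, nor Adrb3, the β3-adrenergic receptor, had a peak within 10 kb of its span in either list. Cidea, a lipid droplet protein, had a boundary peak of 17.4 in the unstimulated list only, while the tallest peaks within 10 kb were 34.3 in the stimulated and 19.7 in the unstimulated list. Nr4a1, an immediate early gene, had no boundary peak, 3 low stimulated peaks over its span and tallest heights of 98.6 and 62.0 within 10 kb.

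**Figure D2:**
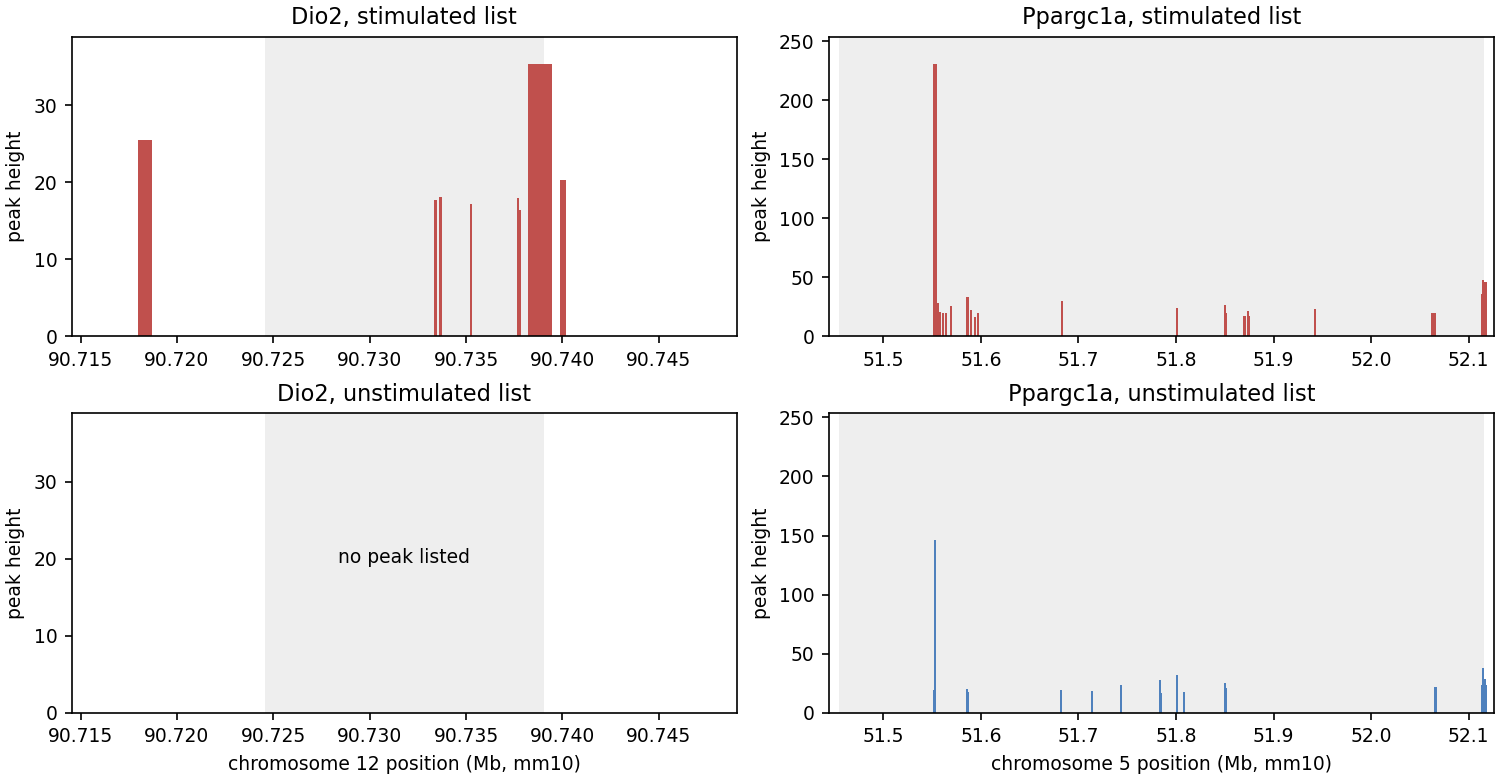
H2A.Z peaks within 10 kb of Dio2 (left) and Ppargc1a (right) in the stimulated (top) and unstimulated (bottom) list, with mm10 position on the x axis in Mb, peak height on the y axis and the annotated gene span shaded. Bars span each peak, and narrow peaks are drawn at a fixed minimum width. Dio2 has no unstimulated peak, and the tallest Ppargc1a peak reaches 230.6 in the stimulated and 146.2 in the unstimulated list.

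Genes of the thermogenic program and of the response to cAMP, the second messenger of the β3-adrenergic receptor, had boundary peaks in the stimulated list only more often than random genes. The random lists were matched on transcript number and gene length, not on carrying a peak. In the thermogenic list, 6 of 30 genes had a boundary peak in the stimulated list only, against a mean of 1.68 in matched random lists (percentile 99.6). They were Dio2, Ffar4 (height 29.1), Cox7a1 (28.5), Otop1 (28.3), Prdm16 and Nrg4 (24.0), while Ppara (25.7) and Cidea had one in the unstimulated list only (2 genes, against a random mean of 0.349, percentile 97.485). One-list genes were thus frequent in both directions, and the unstimulated-only count passed the limit with windows of 2 kb (4 genes against 5 stimulated-only, percentile 99.97), with whole gene spans (99.5) and with unmatched lists (97.7). The Cidea peak, 17.4 tall and 40 bp long, lay near the lowest unstimulated height of 16.0. Of the immediate early genes 9 of 39 were stimulated-only, against 2.05 (percentile 100.0), led by Maff (44.8), Fosl2 (38.8), Zfp36 (34.9), Klf9 (33.8), Jund (31.7) and Bhlhe40 (31.4), and Dusp1 was unstimulated-only (19.9). Of the β-adrenergic and cAMP signalling genes 7 of 39 were stimulated-only, against 2.35 (percentile 99.5). Among them were Prkaca, the catalytic subunit of protein kinase A (39.1), the receptor kinase gene Grk2 (33.8), Adcy9 (30.0), Crtc1 (29.8), Sik1 (20.5) and Rapgef3 (20.1). Of the lipolysis and lipid droplet genes 5 of 30 were stimulated-only, against 1.80 (percentile 98.2), namely Angptl4, an inhibitor of lipoprotein lipase (46.8), the lipases Mgll (28.7) and Pnpla2 (19.5), the lipase inhibitor G0s2 (22.0) and Pck1 (20.5). With rescaled heights the signalling and lipolysis lists no longer stood apart (percentiles 95.2 and 91.2). With windows of 2 kb the immediate early list did not (91.0), and with whole gene spans the thermogenic list did not (96.1).

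Developmental genes kept silent by polycomb in most adult cells were stimulated-only in 8 of 46 cases, against 2.44 (percentile 99.8), among them Hoxa9 (27.8), Sox2 (24.0), Otx2 (22.2), Wt1 (22.2), Nkx6-1 (20.8) and Hoxa13 (18.1). None of the 37 respiratory chain genes was, against 2.16 (percentile 5.46), as 34 of them had boundary peaks in both lists. The remaining lists did not stand apart, with stimulated-only genes such as Ech1 (34.3) in fatty acid oxidation (1 of 25), Srebf1 (27.4) in de novo lipogenesis (1 of 22), Irs2 (35.9) and Gpi1 (21.5) in glucose use (2 of 26), and Atp2a2 and Ryr2 (21.4) in creatine and calcium cycling (2 of 15). Further ones were Mbtd1 (48.5) and Ep400 (18.0) among factors of H2A.Z deposition and removal (2 of 22), Stag2 (23.3), Pds5b (20.7) and Smc1a (19.1) among loop architecture genes (3 of 23), Chac1 (23.2), Hspd1 and Hspe1 (one peak of 18.9) among stress genes (3 of 23), and Rplp0 (29.7) and Ubc (26.5) among housekeeping genes (2 of 18). Srebf1 and Cebpb (18.2) were the 2 of 24 adipocyte transcription factors. A stimulated-only boundary did not exclude unstimulated peaks elsewhere in the gene. Of the 52 stimulated-only genes named from the lists, 9 had peaks of both lists over their span, namely Prdm16, Nrg4, Adcy9, Maff, Srebf1, Hoxa9, Otx2, Ryr2 and Pds5b. The tallest span peak was the unstimulated one in 2 of them, at Ryr2 (35.2 in the stimulated and 46.7 in the unstimulated list) and Pds5b (20.7 and 23.8). Adcy9 had 3 stimulated and 6 unstimulated peaks, the tallest 79.8 and 62.8.

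Where both lists had a boundary peak, thermogenic genes had a larger height ratio than matched genes and adipocyte transcription factors a smaller one. In the thermogenic list the stimulated peak was taller in 13 of 13 genes, with a median log2 ratio of 0.71 against a random range from 0.26 to 0.70 (percentile 98.2). Apart from Pparg, the genes named for this ratio lie outside the naming rule and were chosen after their values were seen. The 3 greatest ratios belonged to Vegfa, the vascular growth factor, with 52.3 and 19.4 in the stimulated and unstimulated list, Esrrg with 45.1 and 21.3 and Zfp516 with 145.4 and 81.3. Esrra (62.1 and 53.4) and Slc16a1 (99.1 and 76.6) were the 2 genes below the median of all genes, with log2 ratios of 0.22 and 0.37. Over whole gene spans the stimulated peak was taller in 17 of 19 genes, with Kcnk3 (22.3 and 26.6) and Bmp8b (19.1 and 26.9) the other way, and Esrrg had 45.1 and 32.9, a log2 ratio of 0.45 just under the median of all genes of 0.46. The percentile was 90.0 with windows of 2 kb and 96.8 with whole gene spans. In the 20 adipocyte transcription factors the median was 0.19 against a random range from 0.30 to 0.68 (percentile 0.07), and 4 exceeded the median of all genes. Cebpa had 159.0 and 140.7 and Nfib 65.5 and 57.4. The unstimulated peak was the taller one in 4 genes, Klf15 (27.9 and 29.7), Nr1h3 (83.0 and 90.5), Zfp467 (65.5 and 73.2) and Nr1d1 (18.8 and 19.3). The 4 above the median were Pparg, Ebf1 (59.1 and 26.0), Rxrb (48.1 and 28.2) and Zfp423 (86.6 and 56.5). Over whole gene spans the tallest peaks of Klf15 (50.2 and 40.7) and Nr1h3 (97.9 and 90.5) were taller in the stimulated list, and those of Ebf1 were 59.1 and 50.0, a log2 ratio of 0.24. Stat5a and Stat5b shared a peak. The other medians lay within the random range, at 0.51 for β-adrenergic signalling (percentile 59.1), 0.59 for immediate early genes (87.5), 0.61 for lipolysis (86.8), 0.63 for fatty acid oxidation (93.2), 0.53 for the respiratory chain (74.2), 0.34 for de novo lipogenesis (4.82), 0.62 for glucose use (93.2) and 0.56 for creatine and calcium cycling (63.0). They were 0.39 for H2A.Z deposition and removal (13.2), 0.37 for loop architecture (14.7), 0.61 for stress genes (88.5), 0.51 for housekeeping genes (52.4) and 0.34 for polycomb targets (37.9). Of 20 lists with a median, 2 lay outside the range from 2.5 to 97.5, where 1 would be by chance. Among the 30 simulated lists without a shift 10.0% did, which is the share observed here. Those lists were few and had their ratios shuffled between genes of all heights. Their share therefore does not settle whether either list stood apart by chance. Across the alternatives the percentile of the adipocyte transcription factors ran from 0.08 to 0.23.

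**Figure D3:**
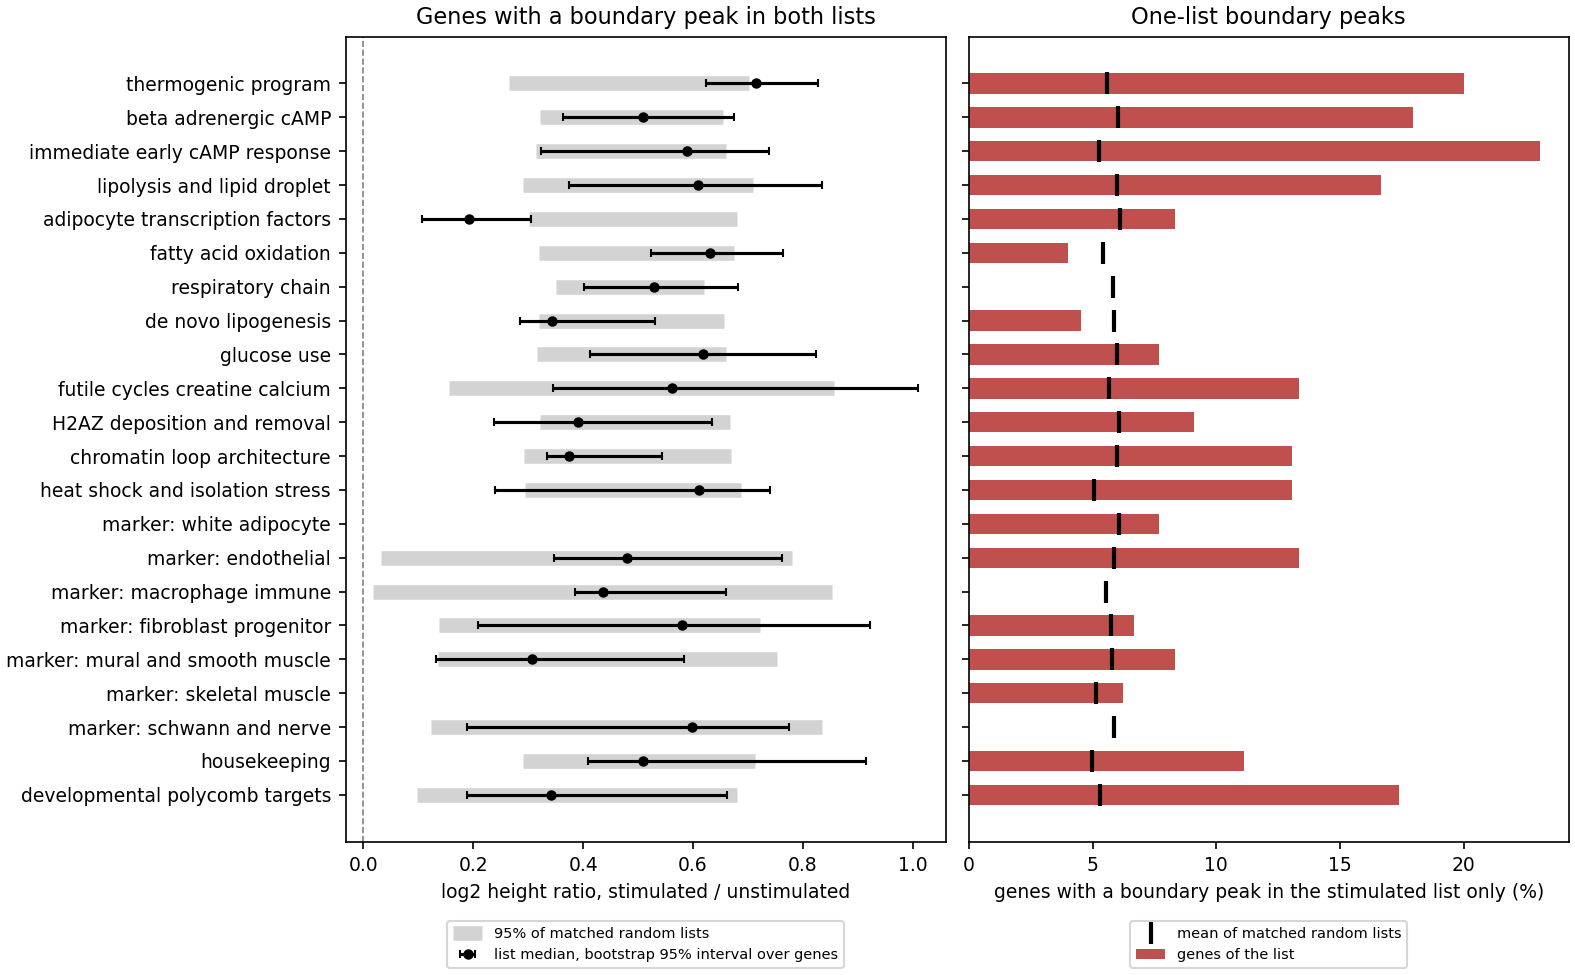
Left, median log2 ratio of stimulated to unstimulated boundary peak height (x axis) for each gene list (y axis), as points with bootstrap 95% intervals over genes, above grey bars holding 95% of matched random lists. Right, percent of each list's genes with a boundary peak in the stimulated list only (bars, x axis) and the mean of random lists (ticks). The thermogenic list lies at 0.71 and the adipocyte transcription factors at 0.19.

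Markers of other cells that tissue isolation could carry along had few H2A.Z peaks where they belonged to immune or muscle cells. A stimulated boundary peak was present in 3 of 20 macrophage and immune markers, against a random mean of 10.6 (percentile 0.015), and in 3 of 16 skeletal muscle markers, against 8.45 (percentile 0.145). Endothelial (9 of 15), fibroblast and progenitor (9 of 15), mural (9 of 12) and Schwann and nerve markers (6 of 12) lay within the range of random lists. White adipocyte markers (3 of 13, against 6.13) lay near its lower end (percentile 3.85). Fabp4 stood in both this list and that of lipolysis and lipid droplets, so the white adipocyte list was not confined to markers of another cell type. Thermogenic genes had a stimulated boundary peak in 19 of 30 cases, against 19.1 (percentile 47.1), and Ucp1 and Adrb3 had none. A missing peak therefore does not show that a cell type was absent. Unstimulated-only peaks marked 2 of 13 white adipocyte markers, Hoxc9 (20.2) and Slc7a10 (18.7; percentile 99.7), and 2 of 20 immune markers, Cd79a (19.3) and Tnf (18.0; percentile 99.2). The first call ended with whole gene spans (percentile 93.2), over which Hoxc9 had a taller stimulated peak (32.3 and 20.2), and the second with windows of 2 kb (89.5). Robo4 (24.3) among endothelial, Myl1 (23.5) among muscle and Rbfox3 (21.1) among nerve markers had such peaks as well, though over its span Myl1 had 54.7 in the stimulated and 34.9 in the unstimulated list. Stimulated-only were Eng (18.2), Erg (18.9), Sncg (22.2), Dpp4 (18.6), Cnn1 (19.3) and Ckm (19.01). Median log2 ratios were 0.48 for endothelial (percentile 64.4), 0.44 for immune (50.0), 0.58 for fibroblast (85.7), 0.31 for mural (18.7) and 0.60 for nerve markers (75.4).

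The larger number of stimulated peaks was spread over the genome, with chromosome X above the autosomes. The ratio of stimulated to unstimulated peaks was 1.33 on X (1762 and 1324 peaks, interval 1.24 to 1.43) and ranged from 1.12 on chromosome 7 to 1.21 on chromosome 2. Unstimulated-only peaks made up 19.6% of the unstimulated peaks on X and 27.2% on the autosomes. Chromosome Y carried 17 stimulated and 12 unstimulated peaks. The median log2 height ratio of shared regions was 0.39 on X and 0.36 on the autosomes.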

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

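The tests on chromosome X were chosen after their results were seen. The height ratio and the rescaling behind the tests on the number and height of peaks were added after the data were seen, though the limits for them were set before their values were known. In each list 2 of the tallest peaks lay at the ends of the mitochondrial sequence, outside the nuclear chromatin that an H2A.Z profile addresses. Near the start, at 100 to 150, heights were 641.2 in the stimulated and 649.3 in the unstimulated list. Near the end, at 16140 in the stimulated and 16130 in the unstimulated list, they were 992.8 and 927.3. The median log2 ratio of these 2 regions was 0.04, against 0.36 over all shared regions.

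For more and taller H2A.Z peaks in the stimulated list, a possible biological explanation is the β3-adrenergic stimulation that the labels name. As read here, the conditions also differ in housing temperature, so effects of the receptor and other effects of housing cannot be told apart. A uniform difference in signal over background, as between libraries of unequal quality or depth, stays open as a technical explanation. The median log2 ratio differed by 0.12 between the second and the highest quartile of mean height (0.35 and 0.47), within the limit of 0.2 set for a single factor. The lowest quartile, at 0.12, lay further off and was left out of that test because its low heights lie near the cutoff of both lists, which limits the ratio. The mitochondrial ratio of 0.04 rests on 2 regions outside nuclear chromatin. A difference in signal over background need not raise such regions, so this ratio does not decide the matter. Whether the cutoff alone set the list lengths stays open as well. After rescaling, stimulated-only peaks stood at 0.729 times the unstimulated-only ones, under the limit of 0.8 set for excluding the cutoff, but that limit was wrong, since rescaling shortened the stimulated list alone to 45413 peaks without calling its peaks again.

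On chromosome X, whether lower heights near the cutoff were the source of the excess of stimulated peaks stays open. The 3 autosomes with a median unstimulated height no greater than that of X had ratios of at most 1.18, below the lower bound of 1.24 for X. No autosome had a ratio above 1.21, so any choice of autosomes would have fallen below that bound. The comparison therefore cannot decide. A different mix of male and female mice in the conditions could shift X, and would move Y the other way. The Y regions lay 0.28 above the autosomes on the log2 scale (bootstrap interval −0.14 to 0.74, 8 regions), too few to decide, so that mix remains open and no biological explanation was tested.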

How the results depend on the processing

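No paired analysis was possible because the lists hold no values per replicate, although the labels number the replicates alike in both groups. For the same reason no replicate could be left out. The limits of −log10 q 5 and fold 4 (which remove no peak), the 5′-most start site and the motif windows were not run. Settings with −log10 p, height, whole gene spans or rescaling, and those of the height ratio, were chosen after seeing the data. Of 367 alternative values for 74 results, 331 kept their side or range, 24 moved, 8 were weaker and 4 stronger. Most of the 331 were percentiles of gene lists that stood apart in neither setting. All 24 that moved were counts, boundary shares or height ratios. Stimulated-only and unstimulated-only counts were scored separately, and their order turned round with rescaling and in the top 10000. The cause of the other shifts was not tested beyond the stricter limits, which remove peaks by construction. In the stimulated and unstimulated list, 32662 and 25941 peaks reached a −log10 p of 20, and 24988 and 19125 a height of 30. Stimulated-only and unstimulated-only peaks numbered 11937 and 3166 with that −log10 p in both lists, 5557 and 1403 with it against the whole other list, 50661 and 40021 with 50% reciprocal overlap, 19714 and 7921 when a peak within 1 kb counted as shared, 18 and 23 among the top 10000, and 13855 and 19008 with rescaled heights. Stimulated-only and unstimulated-only genes numbered 1653 and 141 at a −log10 p of 20 and 887 and 376 after rescaling. The median log2 height ratio was 0.40 at a −log10 p of 20, 0.37 where overlap covered 50% of the shorter peak and 0.47 in the highest quartile. Boundary shares of stimulated-only and unstimulated-only peaks were 14.6% and 9.08% with 1 bp overlap and 21.6% and 16.0% with 2 kb. The thermogenic ratio percentile was 90.0 with 2 kb and 96.8 with gene spans, its stimulated-only percentile 96.1 with gene spans, and its unstimulated-only percentile 99.97 with 2 kb, 97.7 with unmatched lists and 99.5 with gene spans. With 2 kb, immediate early genes had a ratio percentile of 98.97 and a stimulated-only percentile of 91.0, and immune markers an unstimulated-only percentile of 89.5. Rescaling gave stimulated-only percentiles of 95.2 for β-adrenergic signalling and 91.2 for lipolysis, and gene spans an unstimulated-only percentile of 93.2 for white adipocyte markers. Depth is unknown, so its limit on low peaks could not be stated.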

Other observations

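Both tests on the adipocyte transcription factors were chosen after the result was seen. The genes of the next sentences, the 5 with the greatest ratio in each direction, were also chosen after their values were seen, and no theme was tested for them. Among the 10599 genes with boundary peaks in both lists and a mean height of at least 30, the greatest ratio of boundary peaks was found at Pxn, which encodes the focal adhesion protein paxillin, with heights of 143.6 in the stimulated and 19.4 in the unstimulated list (7.38-fold). Glipr1l3 had 127.4 and 19.9, Zfp583 107.4 and 18.9, the cell polarity gene Crb3 101.1 and 17.9, and Casp1, the inflammasome protease, 108.4 and 19.5. In the opposite direction Ccdc15 had 20.4 and 87.4, Abi2 19.3 and 78.6, Car3, a carbonic anhydrase abundant in fat, 27.9 and 107.9, Pkd1l2 22.1 and 72.2, and Wdfy3 20.1 and 61.7. These ratios depend on which peaks fall in the 1 kb windows, and several were not kept by the tallest peak of the whole gene span. Over the span Ccdc15 (95.2 and 87.4), Abi2 (102.2 and 78.6) and Wdfy3 (63.9 and 61.7) had the taller peak in the stimulated list, Car3 had 92.8 and 107.9, and Zfp583 had 107.4 and 89.5, while Pkd1l2 stayed at 22.1 and 72.2. The span values were 143.6 and 24.7 at Pxn (5.81-fold) and 127.4 and 22.5 at Glipr1l3 (5.68-fold), and those of Crb3 and Casp1 were the same as at the boundaries.

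The small height ratio of adipocyte transcription factors was kept when peaks of the whole gene span were used. If annotated boundaries missed the promoters in use, the tallest peak of the whole gene span could return the list to the random range, but its percentile was 0.23. The span includes the boundary windows, so genes with their tallest peaks at a boundary, such as Pparg, kept their value. The tallest span peak also need not mark a promoter, so missed promoters are not excluded. With the peak shared by a pair of genes counted once, 19 genes remained and the percentile was 0.16. Leaving out a single gene can move the median only to a neighbouring value, so this comparison could hardly have come out otherwise. Pparg, Ebf1, Rxrb and Zfp423, the last 3 of them named after their values were seen, were exceptions, with boundary ratios above the median of all genes. No biological explanation was tested, and neither were differences between libraries at these genes.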
